A study of Homo sapiens with 18 samples.

How the data were processed

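RNA from 18 samples of the breast cancer line SKBR3 was hybridized to Illumina expression arrays, 3 arrays for each of 6 groups made of 2 lines (parental, resistant) and 3 treatments (basal, 0.1 µM and 1 µM lapatinib). Groups and replicate numbers were taken from the labels. Per the labels, biotin-labelled cRNA was made from total RNA and signals were exported with BeadStudio, whose version is not given in the sources used here. The deposited non-normalized table holds the probe intensity on a linear scale, with no background subtracted, no detection p-values and no control probes. The deposited normalized table also holds an intensity on a linear scale, quantile-normalized between arrays by the authors as seen from the values, with the same median (84.7) and mean (491.699) in all 18 columns. It was neither centred nor expressed against a control, so higher values mean more signal. Within an array both tables rank probes alike (lowest Spearman rho over arrays 0.9999999846). Each table holds 48803 probes, while the labels state 48697 and describe a gene-level export.

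Values were computed from the non-normalized table with R 4.3.3 and limma 3.58.1. Since negative controls and detection p-values were lacking, the contingency fixed before the data were examined was used, normexp background correction with offset 50, quantile normalization and log2. Because the filter on dim probes was planned on detection p-values, it was replaced by one on the values. On each array, background was the mode of log2 signals with the SD of the values under the mode, and a probe counted as above background beyond the level that a share of 0.05 of such a background exceeds. Probes above background on at least 3 arrays were kept, 22858 in all. The tables list 1 gene symbol for 28098 probes, several for 13 and none for 20692. Symbols were looked up by gene identifier for 28059 probes in a RefSeq table of GRCh38.p14, which was used only for names and for which genes are neighbours. Of the kept probes 16836 had 1 symbol and 6022 had none, and those without were tested only in the probe-level alternative. For the 3284 genes with several kept probes the one with the highest mean signal was used, which left 12587 genes. A gene below background on all arrays of 1 of the groups compared was given as a lower bound against the background level. Of the named results 20 had a group above background on only 1 or 2 of 3 arrays (11 on 1 of 3), and these keep the fitted value, which is not exact.

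A linear model with 1 mean per group was fitted to all 18 arrays (lmFit, contrasts.fit, eBayes with an intensity trend) and 11 contrasts were tested two-sided, with Benjamini-Hochberg adjustment over genes within each contrast and an adjusted p threshold of 0.05. The contrasts were the 2 doses against basal and against each other in each line, the lines against each other at each treatment, and the difference of the responses of the lines at each dose. The replicate number was not a block. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the 29 lists within each contrast, and lists needed 5 measured members. The lists covered ERBB signalling and its targets, proliferation, stress, metabolism, inflammation, breast cell markers, and markers of fibroblasts, leukocytes and endothelium as other cell types. Genes of glucose deprivation and stress touch a theme known from the study of these samples.

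Genes to be named were set by a rule. In the comparisons of 1 µM with basal in each line, of the untreated lines and of the responses at 1 µM, these were the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap between groups. In other comparisons there were 3 of each. Up to 4 members past the threshold were added per list called, and a fixed panel of receptor, stress, cell cycle and drug transport genes. Placeholder names were left out. Genes discussed for their maximum at 0.1 µM and for their place in the genome were chosen after their values were seen.

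The gene test was tested on simulated data for 12587 genes with 50 genes changed at each of 4 fold sizes. For parental 1 µM against basal it recovered 74% at 1.5-fold, 94% at 2-fold, 100% at 3-fold and 98% at 4-fold, with 6 calls among unchanged genes. For the difference between responses at 1 µM it recovered 28%, 86%, 92% and 98%, with 11 such calls. A planted shift of -0.5 in the mitosis list was called, along with 0 of the other lists. The simulated genes varied independently of each other, so false list calls that come from correlated genes were not tested. The genes changed at the 4 fold sizes were few and balanced in direction, and each gene varied equally on every array. In the real data many genes changed and arrays differed in brightness, so recovery and false calls may differ there.

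Alternatives were the authors' normalized values, no background correction, median scaling of arrays, no filter, a stricter filter (a background share of 0.01 on all 3 arrays of a group), the mean of a gene's probes, no intensity trend, array weights, fits to only the groups compared, the replicate number as a block, an adjusted p of 0.01, each array left out in turn, and for lists an estimated correlation and limma's fry. Settings that changed the values or arrays chose the brightest probe again, which moved 1 named gene, SRPK2, to another probe. An offset of 16, a test of every kept probe and, for SRPK2, the first probe kept in 5 such settings were added after seeing the data. The planned block for chip was not run because the tables do not name chips. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.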

Results

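Gene expression was measured in SKBR3, an established human breast cancer cell line with amplified ERBB2, and in a lapatinib-resistant line derived from it. Lapatinib inhibits the kinases of EGFR and ERBB2. Each of the 2 lines was sampled under basal conditions, with 0.1 µM lapatinib and with 1 µM lapatinib, with 3 arrays per group and 18 in all. The length of treatment is not in the labels, nor is whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The mean signal per array fell from 646 ± 25.9 (SD, n = 3) in parental basal samples to 533 ± 21.2 at 0.1 µM and 505 ± 25 at 1 µM, and was 481 ± 40.5, 425 ± 8.16 and 438 ± 8.75 in the resistant line. Background signal lay between 70.1 and 93.7 on the 18 arrays, and the median tested gene lay 2.97 to 3.59 times above it. The number of arrays limits the precision. Replicates correlated at r = 0.986 to 0.996 across genes, which are not independent replicates, and replicate 3 of the resistant line at 0.1 µM stood farthest from its group.

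In all, 12587 genes were tested in 11 comparisons. Quantile normalization gives every array the same distribution, so changes are relative to the middle of the tested genes. The alternative scaled each array by its median over all 48803 probes, of which 35.8% to 40.7% per array were above background. That aligns the arrays near background and not at the middle of the tested genes. Differences in brightness of the tested genes are thus left in. Scaling in this way shifted the log2 changes, and the shift is given here as its median over genes. It was -0.24 in the parental line at 0.1 µM against basal, -0.20 at 1 µM, and -0.10 in the resistant line at 0.1 µM. The same shift was -0.24, -0.10 and -0.11 between the lines at basal, 0.1 µM and 1 µM, and 0.13 in the difference between the responses at either dose. Values under median scaling are given with that shift left in, so a sign can turn there through the shift alone. Relative to the median of all genes under that scaling, the median of every called list kept its sign. Values of single genes are log2 changes ± SE with n = 3 against 3, and p-values are from limma with Benjamini-Hochberg adjustment.

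The first question was what lapatinib at 1 µM changed in the parental, drug-sensitive cells. The largest rises were in CYP4B1, a cytochrome P450 (3.19 ± 0.14, 9.11-fold, adjusted p = 4.19e-15), and MUC1, a mucin of luminal epithelium (2.64 ± 0.14, 6.25-fold). ELAPOR1, an endosomal and lysosomal membrane protein (2.31), FBXO32, a ubiquitin ligase subunit and FOXO target (2.27), VSIG2 (2.25), NUPR1, a stress-induced nuclear protein (2.14), THRSP, a regulator of lipogenesis (2.10), and NCALD, a calcium-binding protein (2.02), followed. The small non-coding RNA SNAR-A1, which has many near-identical copies, fell most but with the widest error (-2.82 ± 0.47). SPRY4, a feedback inhibitor of MAPK signalling, fell (-2.17 ± 0.13), although its other 2 probes gave -0.29 and 0.09. ACAT2, an enzyme of the cholesterol pathway (-1.89, but -0.11 at its other probe), the metallothionein MT2A (-1.84), the ribonucleotide reductase subunit RRM2 (-1.80), PHLDA2 (-1.74), and the cell cycle genes CDCA3 (-1.73) and CDK1 (-1.64) also fell. The rule for naming these 16 genes required all 3 treated arrays to lie beyond all 3 basal arrays.

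Genes of cell division fell together in the treated parental line. Of 40 measured mitosis genes, 38 fell and 0 rose (39 and 0 adjusted over the list alone), with a median of -1.10. Among them were AURKB, a mitotic kinase (-1.55), and BIRC5, a subunit of the same kinase complex (-1.40). Of 34 genes of G1/S and DNA replication, 32 fell and 0 rose (32 and 0 adjusted over the list alone), such as UHRF1 (-1.57), POLE2 (-1.49) and CDC45 (-1.43). Nucleolar and MYC target genes fell in 20 of 29 members, with 0 rises (21 and 0 adjusted over the list alone), led by ODC1, the first enzyme of polyamine synthesis (-1.51), with the ribosome assembly factors PPAN (-0.73), NOP16 (-0.63) and UTP4 (-0.56). ERBB-MAPK feedback and immediate early genes fell in 11 of 21 members, with 0 rises (11 and 0 adjusted over the list alone), including EGR1 (-1.13), DUSP4 (-0.94) and CCND1, which encodes cyclin D1 (-0.91). These 4 lists stood apart from other genes in limma's camera test, with adjusted p = 2.13e-37, 1.43e-27, 7.44e-09 and 2.99e-05, and held with an estimated correlation (0.000234, 0.000288, 0.000481 and 0.00162).

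Targets of FOXO transcription factors, lysosomal genes and luminal markers moved the other way. Of 27 FOXO targets, 18 rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 2.18e-13), including TXNIP, an inhibitor of glucose uptake (1.92), the repressor BCL6 (1.79) and PDK4, a kinase that blocks pyruvate dehydrogenase (1.52, fitted, with 1 of 3 basal arrays above background). Of 30 lysosome and autophagy genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 2.77e-07), including the autophagy kinase gene ULK1 (1.04), GABARAPL1 (0.92), the acid glucosidase GAA (0.87) and MAP1LC3B (0.86). Of 22 luminal markers, 9 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.00122), including PIP (1.12), the tight junction gene CLDN3 (0.94) and the transcription factor ELF3 (0.86). Genes of NF-kB and inflammatory cytokines fell in 8 of 21 members, with 0 rises (8 and 0 adjusted over the list alone, adjusted p = 0.00506), including S100A7 (-1.35), S100A8 (-1.27) and S100A9 (-1.02). CXCL8, a neutrophil chemokine that was not above background at 1 µM, fell at least 1.77-fold. These 4 lists also held with an estimated correlation (adjusted p = 0.00162, 0.000481, 0.0466 and 0.0466).

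Glycolysis genes fell in 9 and rose in 3 of 26 members (13 and 3 adjusted over the list alone, camera adjusted p = 0.0276), including LDHA (-0.83), PGAM1 (-0.64), PKM (-0.63) and ALDOC (-0.59). That call was lost with an estimated correlation (adjusted p = 0.204) and when a gene's probes were averaged (0.0905), and the list touches a theme the study is known to have raised from these samples, so it is not independent evidence. Cholesterol synthesis genes fell in 9 and rose in 2 of 20 members (9 and 2 adjusted over the list alone, adjusted p = 0.0222), including INSIG1 (-0.70), SQLE (-0.70) and EBP (-0.68), and that call too was lost (adjusted p = 0.0689 with an estimated correlation). Among genes fixed as a panel, ERBB3, a partner receptor of ERBB2, rose (1.06 ± 0.10, adjusted p = 2.08e-09), but its other 2 probes gave 0.01 and 0.06. The proliferation marker MKI67, above background on 1 of 3 treated arrays, fell (fitted -0.68 ± 0.13, adjusted p = 0.000285). DDIT3, a stress-induced transcription factor, rose (0.44, adjusted p = 0.00334), a call that ended under median scaling (0.28, adjusted p = 0.0625). ERBB2 was at the edge of the threshold (0.29, adjusted p = 0.0479), and its call ended without parental 1 µM replicate 1, 2 or 3 (adjusted p = 0.082, 0.15 and 0.0813) or parental basal replicate 2 or 3 (0.115 and 0.272). It also ended under median scaling (0.12, adjusted p = 0.414), with the mean of its probes (0.17, adjusted p = 0.217) and without a filter (adjusted p = 0.0588), so a rise of ERBB2 was not established. EGFR (0.25, adjusted p = 0.0684) and the ER chaperone HSPA5 (0.21, adjusted p = 0.132) did not pass.

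In numbers, 3503 genes passed an adjusted p of 0.05 in limma, 1797 higher and 1706 lower with drug, of which 149 and 128 changed at least 2-fold. Groups did not overlap in 42.6% of tested genes, against 10% by chance for 3 against 3. With median scaling the count was 4340, split into 763 higher and 3577 lower.

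**Figure D1:**
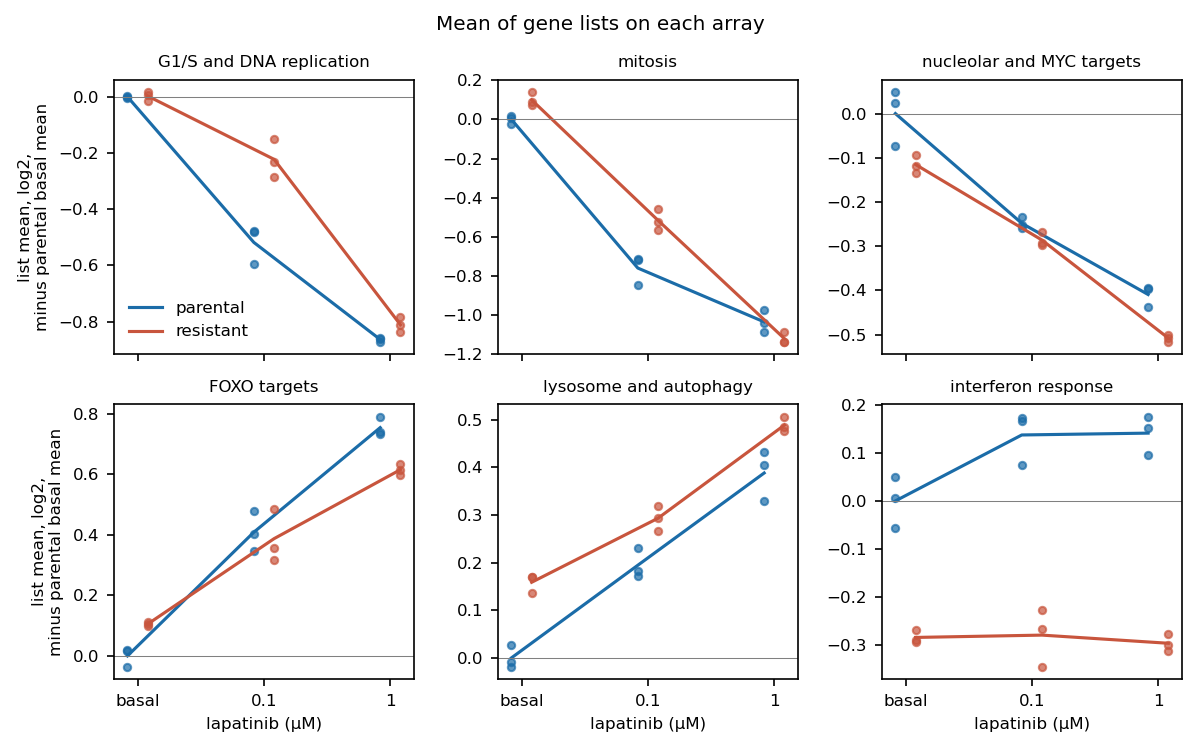
Mean log2 signal of 6 gene lists on each of the 18 arrays, minus the parental basal mean (y axis), by lapatinib dose in µM (x axis), with points for arrays, lines through group means, and the parental line in blue and the resistant in red. At 1 µM the mitosis list reached -1.04 in the parental and -1.12 in the resistant line and FOXO targets 0.75 and 0.62. Some list medians, which are not plotted, changed sign under median scaling. These were the small rises of the lysosomal and interferon lists in parental cells at 0.1 µM, and the lysosomal gap between the untreated lines. Relative to the median of all genes under that scaling, the medians of the lists kept their sign.

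The next comparison asked whether the resistant line still responded to 1 µM. CYP4B1 again rose most (2.87 ± 0.14, 7.32-fold, adjusted p = 1.16e-13). The membrane protein TMEM176A (2.36), the protease inhibitor SPINK8 (2.03), ELAPOR1 (1.98), MUC1 (1.94), VSIG2 (1.84) and ENPP2, the enzyme that makes lysophosphatidic acid (1.82), also rose. SRPK2, a splicing factor kinase, rose at its brightest probe (1.85), but its other 2 probes gave 0.27 and 0.45. Under median scaling and without resistant 1 µM replicate 2 or 3 another of its probes became the brightest, and its call ended (0.36, 0.39 and 0.33, adjusted p = 0.0937, 0.0906 and 0.133). With the first probe kept, a check chosen after seeing the data, the same settings gave 1.72, 1.78 and 1.82 (adjusted p up to 4.15e-09), so the result for SRPK2 depended on the probe. The largest falls were in UHRF1, which maintains DNA methylation at replication (-2.08 ± 0.11, 4.24-fold, adjusted p = 3.82e-13), KIF20A, a mitotic kinesin (-1.89), and SPRY4 (-1.83, but -0.14 and 0.01 at its other 2 probes). PTTG1, which encodes securin (-1.80), KIFC1 (-1.79), RRM2 (-1.64), CDCA3 (-1.62) and the cell cycle transcription factor FOXM1 (-1.60) fell as well. By the same rule, these 16 genes were named only because all 3 treated arrays lay beyond all 3 basal arrays.

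All 40 mitosis genes fell in the resistant line (40 also adjusted over the list alone), with a median of -1.25 and camera adjusted p = 3.04e-52. G1/S and DNA replication genes fell in 30 of 34 members, with 0 rises (32 and 0 adjusted over the list alone, adjusted p = 5.53e-28), including MCM10 (-1.52) and E2F2 (-1.43). ERBB-MAPK feedback and immediate early genes fell in 14 of 21 members, with 0 rises (16 and 0 adjusted over the list alone, adjusted p = 3.1e-09), including EGR1 (-1.55), CCND1 (-0.98) and JUN (-0.89). Nucleolar and MYC targets fell in 21 of 29, with 0 rises (21 and 0 adjusted over the list alone, adjusted p = 4.66e-09), including ODC1 (-1.46), the pyrimidine synthesis enzyme CAD (-0.72), MRTO4 (-0.68) and NOP16 (-0.57). FOXO targets rose in 17 and fell in 1 of 27 (18 and 1 adjusted over the list alone, adjusted p = 1.19e-09), including TXNIP (1.58), FBXO32 (1.44), YPEL3 (1.36) and BCL6 (1.18). Lysosome and autophagy genes rose in 15 and fell in 1 of 30 (16 and 1 adjusted over the list alone, adjusted p = 4.78e-07), including GABARAPL1 (0.90), CTSA (0.83), WIPI1 (0.82) and NEU1 (0.76). Luminal markers rose in 11 and fell in 1 of 22 (11 and 1 adjusted over the list alone, adjusted p = 0.000156), including PIP (0.77), ELF3 (0.76) and CLDN3 (0.67). NF-kB and inflammatory cytokine genes fell in 7 and rose in 1 of 21 (7 and 1 adjusted over the list alone, adjusted p = 0.00443), including S100A9 (-1.05), S100A8 (-1.01), S100A7 (-0.72) and TNF (-0.67). All 8 lists held with an estimated correlation, with the highest adjusted p = 0.0437 for the NF-kB list.

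Of the panel, ERBB3 rose in the resistant line as well (0.76 ± 0.10, adjusted p = 7.16e-07), with 0.09 and 0.23 at its other 2 probes. MKI67 fell (-0.50, adjusted p = 0.00674), a call that ended without resistant 1 µM replicate 3 (-0.41, adjusted p = 0.054). ERBB2 (0.10, adjusted p = 0.587), EGFR (0.25, adjusted p = 0.08), HSPA5 (-0.08, adjusted p = 0.628) and DDIT3 (0.03, adjusted p = 0.883) did not pass. In limma, 2892 genes passed, 1372 higher and 1520 lower, 96 and 132 of them at least 2-fold, and groups did not overlap in 38.0% of genes against 10% by chance. Median scaling gave 2601, split into 750 higher and 1851 lower.

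The responses of the 2 lines at 1 µM shared no arrays and correlated across genes at r = 0.772 (Spearman rho = 0.647). Of the genes called, 952 rose in both lines, where independent lists would share 196, and 997 fell in both, against 206. In opposite directions, 18 genes passed in both lines. At 0.1 µM the correlation was 0.575 (rho = 0.455), with 302 shared rises against 29.7 and 214 shared falls against 22.1.

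The central question of the series is how the resistant line differs from its parent, here without drug. The cancer-testis genes PAGE5 (5.53 ± 0.22, 46.1-fold, adjusted p = 8.93e-17), PAGE2 (5.51) and PAGE2B (5.40) were far higher in the resistant line. Their sequences are near-identical, so the 3 signals cannot be separated, and 1 of the 2 other PAGE5 probes gave only 0.18. The actin-severing protein SCIN (4.09), the embryonic globin HBE1 (2.94) and the fetal globin HBG2 (2.32) were also higher. NLGN4X, a synaptic adhesion molecule, was higher as well (2.62, with 0.40 and 1.06 at its other 2 probes). It was above background on 1 of 3 parental arrays, so 2.62 is not exact. PARVB, a focal adhesion protein that was not above background in the parental line, was at least 4.10-fold higher, with 0.14 at its other probe.

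Lower in the resistant line were CYP1B1, an oestrogen-metabolizing cytochrome P450 (-3.33 ± 0.15, adjusted p = 1.06e-15), KLHL13, a ubiquitin ligase adaptor (-3.11), and CFD, complement factor D (-2.71). The elastase inhibitor PI3 (-2.67), the zinc finger gene ZNF704 (-2.52), BASP1 (-2.05) and ITPRIPL2 (-2.03) were lower too. CHN1, a Rac-directed GTPase activator, was not above background in the resistant line and was at least 3.75-fold lower. As the naming rule required, all 3 arrays of each line lay apart in these 16 genes. HSPA5, the main chaperone of the endoplasmic reticulum, was higher (1.06 ± 0.10, adjusted p = 8.36e-09), and so was TXNIP (0.83, adjusted p = 1.24e-05).

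No receptor of the panel passed between the untreated lines. ERBB2 differed by 0.17 (adjusted p = 0.356), EGFR by 0.04 (adjusted p = 0.874), MET by -0.13 (adjusted p = 0.596) and ERBB3 by 0.07 (adjusted p = 0.717), where its other 2 probes gave -0.31 and -0.25. ESR1 (-0.16, adjusted p = 0.499) and the efflux pump ABCB1 (0.02, adjusted p = 0.948) lay near background, while ABCG2 and AXL were too dim to test. DDIT3 (-0.01, adjusted p = 0.976) and MKI67 (-0.003, adjusted p = 0.994) did not pass. CCND1 was higher (0.31, adjusted p = 0.0207), but median scaling turned its direction (-0.10, adjusted p = 0.546). Its call also ended without parental basal replicate 2 (adjusted p = 0.0511), parental basal replicate 3 (0.0802) or resistant basal replicate 2 (0.0935).

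Interferon response genes were lower in 12 and higher in 1 of 30 members in untreated resistant cells (13 and 1 adjusted over the list alone, camera adjusted p = 0.000643, and adjusted p = 0.0587 with an estimated correlation). Examples were the guanylate-binding proteins GBP1 (-1.09) and GBP2 (-0.83), the antigen peptide transporter TAP1 (-1.02) and BST2 (-0.75). NF-kB and inflammatory cytokine genes were lower in 6 of 21 and higher in 0 (6 and 0 adjusted over the list alone, adjusted p = 0.00491, and adjusted p = 0.0643 with an estimated correlation), including the chemokine CCL5 (-1.03), S100A7 (-0.82) and S100A9 (-0.82). CXCL8 was above background on 1 of 3 resistant arrays, so its fitted -0.90 is not exact. Lysosome and autophagy genes were higher in 8 of 30 and lower in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.0194, and adjusted p = 0.0643 with an estimated correlation), including GAA (0.92), CTSF (0.50), NPC1 (0.46) and MAP1LC3B (0.42). The lysosomal median of 0.12 turned to -0.16 under median scaling (0.03 relative to the median of all genes), which also ended the list's call (adjusted p = 0.502) and those of CTSF, NPC1 and MAP1LC3B.

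In the same comparison 1946 genes passed in limma, 909 higher and 1037 lower in resistant cells, with 57 and 79 at least 2-fold apart and 33.6% of genes with groups that did not overlap (10% by chance). Median scaling gave 4167, split into 315 higher and 3852 lower. Of the genes called at each treatment, 423 were higher in the resistant line at all 3 treatments, where independent lists would share 8.22, and 540 were lower, against 12.8.

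**Figure D2:**
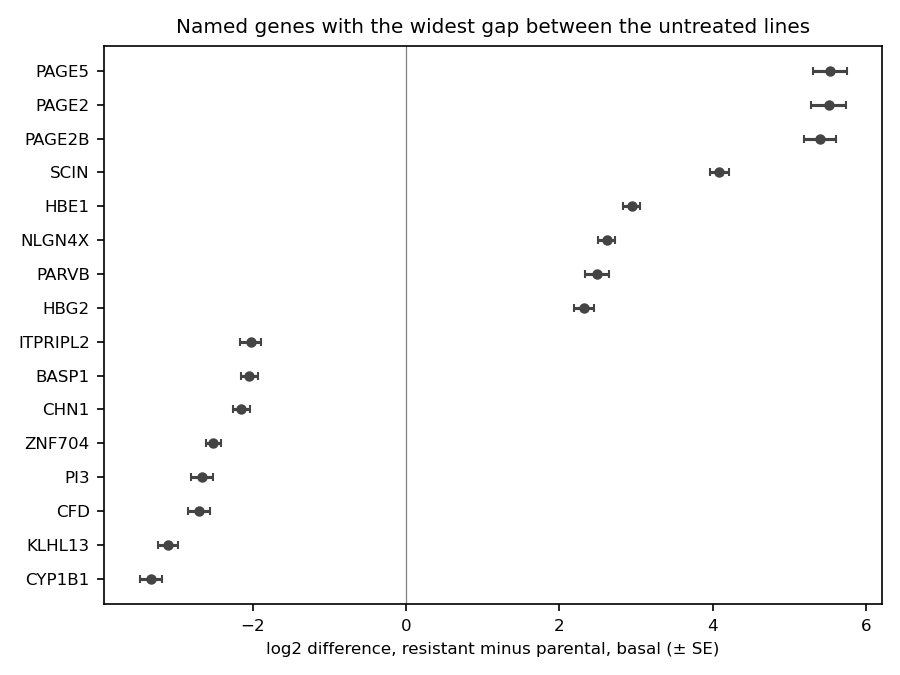
Log2 difference between the untreated lines, resistant minus parental (x axis, points with SE bars, n = 3 against 3), for the 16 genes named as furthest apart (y axis), from -3.33 for CYP1B1 to 5.53 for PAGE5. PARVB and CHN1 were not above background in one line, so their plotted fitted values are not bounds, and their folds were at least 4.10 and at least 3.75.

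With drug, the PAGE genes stayed on top. At 0.1 µM PAGE2 (5.69), PAGE5 (5.33) and PAGE2B (5.27) were higher and KLHL13 (-3.30), CFD (-2.90) and PI3 (-2.80) lower, and at 1 µM PAGE2 (5.47), PAGE2B (5.40) and PAGE5 (5.21) against CYP1B1 (-3.57), KLHL13 (-3.25) and CFD (-3.23). Interferon response genes were lower in 15 and higher in 0 of 30 at 0.1 µM (17 and 0 adjusted over the list alone, adjusted p = 1.93e-07), including TAP1 (-1.32), GBP1 (-1.31), IRF1 (-0.98) and BST2 (-0.93). At 1 µM 16 were lower and 0 higher (17 and 0 adjusted over the list alone, adjusted p = 9.19e-07), including TAP1 (-1.50), GBP1 (-1.35), IRF1 (-1.22) and IRF7 (-1.02). Both calls held with an estimated correlation (adjusted p = 0.00586 and 0.00738). MET, which had not passed without drug, was lower at 1 µM (-0.47, adjusted p = 0.0137), but that call ended without parental 1 µM replicate 1 (-0.35, adjusted p = 0.106) or resistant 1 µM replicate 2 (-0.32, adjusted p = 0.129). The test of the difference between its responses did not pass (-0.34, adjusted p = 0.495).

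ER chaperone genes were higher in 10 and lower in 2 of 30 at 0.1 µM (10 and 2 adjusted over the list alone, adjusted p = 0.00609, and adjusted p = 0.0971 with an estimated correlation), with a median of 0.19 that median scaling turned to -0.04. Members included HYOU1 (0.81), SEC24D (0.81), HSPA5 (0.80) and WFS1 (0.78). At 1 µM 13 were higher and 2 lower (13 and 4 adjusted over the list alone, adjusted p = 0.0048, and adjusted p = 0.111 with an estimated correlation), including SEC24D (1.15), HYOU1 (0.85), HSPA5 (0.77) and SDF2L1 (0.67). Glycolysis genes were higher in 10 and lower in 2 of 26 at 0.1 µM (11 and 3 adjusted over the list alone, adjusted p = 0.0072, and adjusted p = 0.139 with an estimated correlation), with a median of 0.20 that median scaling turned to -0.0042. Both lists touch a theme the study is known to have raised from these samples, so neither is independent evidence.

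Other lists apart at 0.1 µM were G1/S and DNA replication, higher in 16 of 34 and lower in 0 (18 and 0 adjusted over the list alone, adjusted p = 1.93e-07, and adjusted p = 0.0509 with an estimated correlation), and mitosis, higher in 12 of 40 and lower in 0 (13 and 0 adjusted over the list alone, adjusted p = 1.13e-05, and adjusted p = 0.0971 with an estimated correlation). Cholesterol synthesis genes were higher in 8 and lower in 1 of 20 at 0.1 µM (9 and 1 adjusted over the list alone, adjusted p = 0.00556, and adjusted p = 0.0521 with an estimated correlation). At 1 µM 7 were higher and 0 lower (8 and 0 adjusted over the list alone, adjusted p = 0.0218, and adjusted p = 0.111 with an estimated correlation). NF-kB genes were lower in 8 and higher in 0 of 21 at 0.1 µM (8 and 0 adjusted over the list alone, adjusted p = 0.00143, and adjusted p = 0.0509 with an estimated correlation). At 1 µM 6 were lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.0461, and adjusted p = 0.205 with an estimated correlation). In all, 2531 genes passed at 0.1 µM, 1228 higher and 1303 lower, and 2663 at 1 µM, 1166 higher and 1497 lower. Median scaling gave 2596 (475 higher, 2121 lower) and 2700 (522 higher, 2178 lower).

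Whether the lines responded differently to 1 µM was tested as the resistant minus the parental response. PDK4 rose in parental cells (1.52) and changed by 0.31 in resistant cells, a difference of -1.20 ± 0.18 (adjusted p = 0.00145). These fitted values are not exact, since PDK4 was above background on 1 of 3 untreated parental and 2 of 3 untreated resistant arrays. LRRC31 rose by 1.84 and 0.66 (difference -1.18, adjusted p = 0.000611), MAL, a raft-associated membrane protein, by 1.85 and 0.79 (-1.05, adjusted p = 0.000378), and BNIPL by 1.64 and 0.59 (-1.05, adjusted p = 0.0103, with 0.07 at its other probe). The cholesterol exporter ABCA1 rose by 1.72 in parental cells. It was not above background in untreated resistant cells, so its fitted change there (0.80) and the difference (-0.92) are not exact, and that call ended with offset 16 (-0.93, adjusted p = 0.106). SPRED1, an inhibitor of RAS-MAPK signalling, changed by -0.002 in parental and -0.88 in resistant cells (-0.88, adjusted p = 0.00311). JPH2 changed by -0.27 and -1.28 (-1.01), and the non-coding RNA MIR503HG by 0.09 and -0.92 (-1.01).

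In the other direction, TARP, a T-cell receptor gamma reading frame, changed by -0.28 in parental and 0.89 in resistant cells (1.16 ± 0.16, adjusted p = 0.000434). SSR3, a subunit of the ER translocon-associated complex, changed by -0.48 and 0.64 (1.12, adjusted p = 0.0117), and PDIA3P1, a pseudogene that shares sequence with the disulfide isomerase gene PDIA3, by -0.51 and 0.41 (0.92, adjusted p = 0.00201). GINS4, a replication helicase subunit, changed by -1.11 and -0.09 (1.02), and the urea cycle enzyme CPS1 by -1.24 and -0.27 (0.97, adjusted p = 0.00585). ANKRD37 changed by -0.05 and 0.88 (0.93). GSTA3 changed by 0.98 in resistant cells, but it was not above background in parental cells, so the difference (0.97) is not exact. Its other probe gave -0.04, and the mean of its probes ended the call (0.47, adjusted p = 0.161). ACOX2 changed by -1.21 in parental cells, where it was not above background at 1 µM, and was not above background in resistant cells. Its difference (0.89) is no measured size and no bound, and offset 16 ended the call (1.16, adjusted p = 0.0834).

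FOXO targets responded less in the resistant line, with 2 of 27 lower, PDK4 and FBXO32 (2.27 and 1.44, difference -0.83), and 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.000132, and adjusted p = 0.16 with an estimated correlation). Mitosis genes differed in 2 of 40, KIF20A (-1.19 and -1.89, difference -0.70) and CDC25B (0.23 and -0.54, difference -0.77), with 0 higher (4 and 0 adjusted over the list alone, adjusted p = 0.00106, and adjusted p = 0.264 with an estimated correlation). ATF4 and amino acid response genes differed in 2 of 29, the asparagine synthetase ASNS (0.66 and -0.04, difference -0.70) and DDIT4 (0.39 and -0.20, difference -0.59), with 0 higher (3 and 0 adjusted over the list alone, adjusted p = 0.00654, and adjusted p = 0.16 with an estimated correlation). The medians of the mitosis and ATF4 lists, -0.20 and -0.15, turned to 0.02 and 0.02 under median scaling. Relative to the median of all genes they were -0.07 and -0.07 there. Glycolysis genes differed in 1 member each way (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0445, and adjusted p = 0.264 with an estimated correlation), with ALDOA at 0.75 (-0.31 and 0.44), although its other 3 probes gave -0.18 to 0.15. Interferon response genes differed in 0 members (4 lower and 0 higher adjusted over the list alone, adjusted p = 0.0218, and adjusted p = 0.172 with an estimated correlation). The ATF4 and glycolysis lists touch a theme the study is known to have raised from these samples, so they are not independent evidence. No panel gene passed, with ERBB2 at -0.19 (adjusted p = 0.657), EGFR at -0.002 (0.999), ERBB3 at -0.30 (0.363), HSPA5 at -0.29 (0.408), DDIT3 at -0.41 (0.261), CCND1 at -0.07 (0.888), MKI67 at 0.18 (0.754) and TXNIP at -0.34 (0.417).

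In limma, 87 genes passed, 40 with a higher and 47 with a lower response in resistant cells (1556 at an unadjusted p under 0.05), and of them 3 and 7 differed at least 2-fold. The change was larger in the parental line in 53 and in the resistant line in 34. Median scaling gave 71 genes, 63 higher and 8 lower, so the balance of directions depended on that choice. Of the 22 named genes, 13 passed without any 1 of the 12 arrays, while GINS4, ANKRD37, MIR503HG, ABCA1, CDC25B, KIF20A, ASNS, DDIT4 and ALDOA did not, with adjusted p up to 0.139. Median scaling ended the calls of SPRED1 (-0.67, adjusted p = 0.0772), FBXO32 (-0.60, 0.0885), MIR503HG (-0.84, 0.103), CDC25B (-0.59, 0.129), KIF20A (-0.50, 0.165), ASNS (-0.48, 0.224) and DDIT4 (-0.37, 0.369). The mean of a gene's probes ended those of BNIPL (-0.49, adjusted p = 0.209), ASNS (-0.50, 0.285) and ALDOA (0.21, 0.521), among others. At 0.1 µM only LRRC31 passed (-1.02 ± 0.17, adjusted p = 0.0218), with 1067 genes at an unadjusted p under 0.05. That call ended on leaving out 1 array for 6 of the 12 arrays (adjusted p = 0.0527 to 0.148) and when only the groups compared were fitted (adjusted p = 0.0613). Median scaling gave 5 genes, 4 higher and 1 lower.

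**Figure D3:**
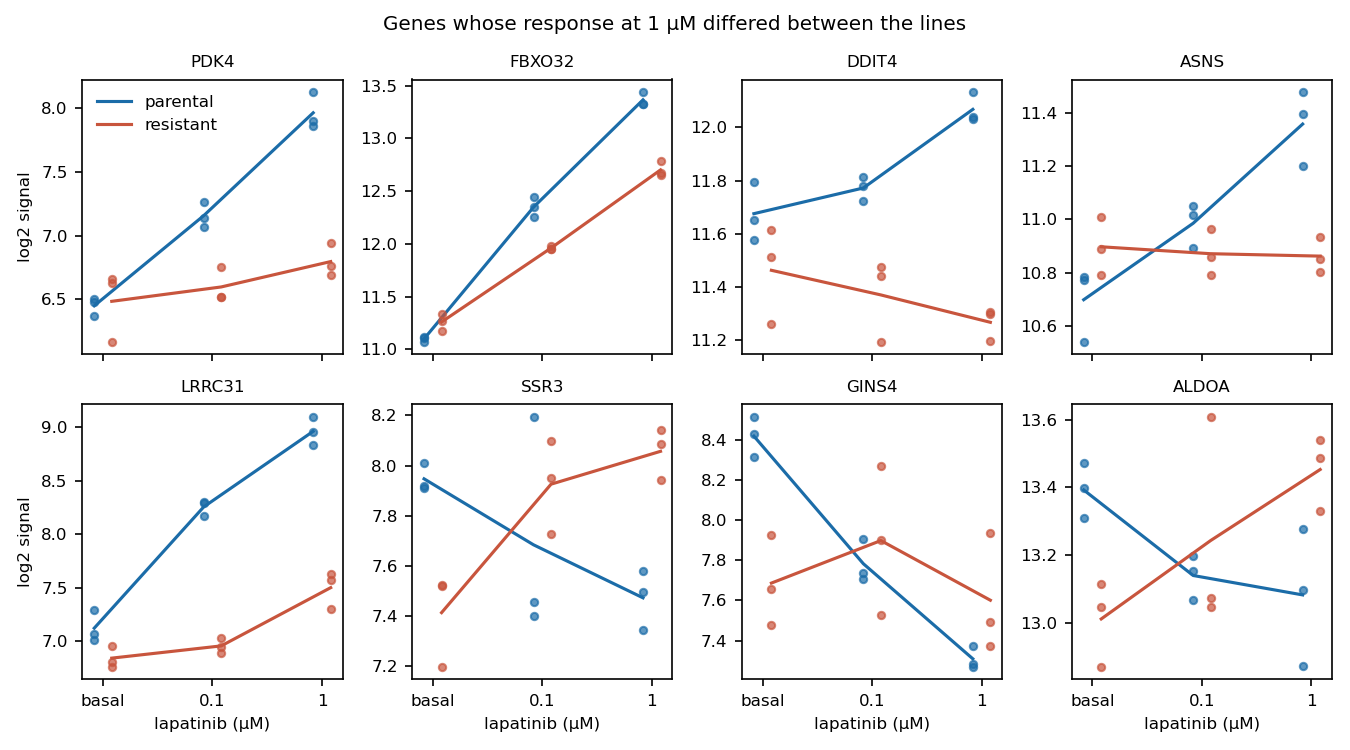
Normalized log2 signal (y axis, on a separate scale for each gene) of 8 genes with a different response at 1 µM, by lapatinib dose in µM (x axis), with points for arrays, lines through group means, and the parental line in blue and the resistant in red. From basal to 1 µM PDK4 changed by 1.52 in parental and 0.31 in resistant cells and SSR3 by -0.48 and 0.64, while GINS4, DDIT4, ASNS and ALDOA each lost the call without at least 1 array.

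The list differences at 0.1 µM went with 0 members past the test in each list. G1/S and DNA replication genes fell less in resistant cells, with a median difference of 0.30 (8 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.51e-13, and adjusted p = 0.0152 with an estimated correlation). The other calls were lost with an estimated correlation. Mitosis had a median difference of 0.14 (3 and 0 adjusted over the list alone, adjusted p = 0.00132, and adjusted p = 0.225 with an estimated correlation) and glycolysis 0.21 (1 and 0 adjusted over the list alone, adjusted p = 0.00156, and adjusted p = 0.131 with an estimated correlation). FOXO targets were at -0.09 (0 higher and 2 lower adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.25 with an estimated correlation), interferon genes at -0.16 (0 and 1 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.142 with an estimated correlation) and receptor tyrosine kinases and ERBB ligands at -0.12 (0 and 1 adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.131 with an estimated correlation).

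At the lower dose of 0.1 µM against basal, the parental line raised CYP4B1 (1.87), VSIG2 (1.65) and MUC1 (1.56) and lowered RRM2 (-1.28), ACAT2 (-1.21) and CCNA2, which encodes cyclin A2 (-1.15). Mitosis genes fell in 38 of 40 with 0 rises (39 and 0 adjusted over the list alone, adjusted p = 1.68e-48), replication genes in 24 of 34 with 0 rises (32 and 1 adjusted over the list alone, adjusted p = 1.33e-25) and nucleolar genes in 8 of 29 with 0 rises (13 and 0 adjusted over the list alone, adjusted p = 6.23e-07). FOXO targets rose in 15 and fell in 1 of 27 (17 and 1 adjusted over the list alone, adjusted p = 2.23e-11), and NF-kB genes fell in 5 and rose in 0 of 21 (6 and 0 adjusted over the list alone, adjusted p = 0.00451). Luminal markers rose in 7 and fell in 0 of 22 (7 and 0 adjusted over the list alone, adjusted p = 0.000416), and lysosomal genes rose in 6 and fell in 0 of 30 (8 and 0 adjusted over the list alone, adjusted p = 0.000241), both with medians, 0.15 and 0.18, that median scaling turned to -0.0028 and -0.07. These 7 held with an estimated correlation, with adjusted p up to 0.0472, but median scaling ended the lysosomal call (adjusted p = 0.0966). Lost were glycolysis (1 rose and 5 fell, 1 and 6 adjusted over the list alone, adjusted p = 0.0218, adjusted p = 0.151 with an estimated correlation), again not independent evidence, cholesterol synthesis (1 rose and 5 fell, 2 and 7 adjusted over the list alone, adjusted p = 0.0334, adjusted p = 0.0952 with an estimated correlation) and NRF2 targets (1 rose and 3 fell, 1 and 4 adjusted over the list alone, adjusted p = 0.0334, adjusted p = 0.0952 with an estimated correlation). Interferon genes were also lost (3 rose and 0 fell, 3 and 0 adjusted over the list alone, adjusted p = 0.0334, adjusted p = 0.116 with an estimated correlation), with a median of 0.12 that median scaling turned to -0.06. In limma 1415 genes passed, 744 higher and 671 lower, and with median scaling 3642, split into 239 and 3403.

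The resistant line at 0.1 µM raised CYP4B1 (2.08), MUC1 (1.42) and the MAPK phosphatase DUSP1 (1.32) and lowered MT2A (-1.11, adjusted p = 0.0787 when only the groups compared were fitted), SPRY4 (-1.10) and EXOG (-1.07). Mitosis genes fell in 36 of 40 with 0 rises (40 and 0 adjusted over the list alone, adjusted p = 2.57e-45) and replication genes in 7 of 34 with 0 rises (12 and 0 adjusted over the list alone, adjusted p = 7.75e-08). FOXO targets rose in 10 and fell in 1 of 27 (14 and 2 adjusted over the list alone, adjusted p = 4.74e-08), luminal markers rose in 3 and fell in 0 of 22 (6 and 0 adjusted over the list alone, adjusted p = 0.000452), and lysosomal genes rose in 6 and fell in 0 of 30 (8 and 2 adjusted over the list alone, adjusted p = 0.00394). NF-kB genes fell in 7 and rose in 0 of 21 (7 and 0 adjusted over the list alone, adjusted p = 0.000188) and nucleolar genes fell in 2 and rose in 0 of 29 (2 and 0 adjusted over the list alone, adjusted p = 0.000188). All 7 held with an estimated correlation, with adjusted p up to 0.0317, but median scaling ended the lysosomal call (adjusted p = 0.142). In limma 916 genes passed, 502 higher and 414 lower, and with median scaling 1040, split into 155 and 885. The count fell to 577 (321 higher) with array weights and to 279 (154 higher) with only the groups compared fitted.

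Between 0.1 µM and 1 µM the parental line raised CYP4B1 (1.32), ABCA1 (1.19) and MUC1 (1.09) and lowered SNAR-A1 (-2.57), EGR1 (-2.12) and SPRY4 (-1.31). ERBB-MAPK genes fell in 7 of 21 (12 adjusted over the list alone, adjusted p = 2.43e-10), replication genes in 15 of 34 (24, 2.04e-18), mitosis genes in 11 of 40 (21, 9.75e-13) and nucleolar genes in 2 of 29 (2, 0.000136), each with 0 rises. FOXO targets rose in 12 of 27 (15 adjusted over the list alone, adjusted p = 1.14e-12) and lysosomal genes in 8 of 30 (11, 1.74e-05), each with 0 falls, and these 6 lists held with an estimated correlation (adjusted p up to 0.00731). ATF4 targets rose in 4 and fell in 0 of 29 (7 and 1 adjusted over the list alone, adjusted p = 0.00506, adjusted p = 0.0591 with an estimated correlation), a list that is not independent evidence. In limma 692 genes passed, 388 higher and 304 lower, with median scaling 379 (227 higher), and with only the groups compared fitted 1195 (592 higher).

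The same dose step in the resistant line raised TMEM176A (1.22), SOCS2, a suppressor of cytokine signalling (1.15), and SPINK8 (1.06) and lowered EGR1 (-2.23), FOS (-1.56, above background on 1 of 3 arrays at 1 µM) and DUSP1 (-1.27). Replication genes fell in 25 of 34 (28 adjusted over the list alone, adjusted p = 1.23e-37), mitosis genes in 33 of 40 (37, 3.33e-44), ERBB-MAPK genes in 11 of 21 (12, 3.88e-11) and nucleolar genes in 6 of 29 (13, 7.51e-07), each with 0 rises. FOXO targets rose in 7 and fell in 0 of 27 (13 and 1 adjusted over the list alone, adjusted p = 7.51e-07) and lysosomal genes rose in 3 and fell in 1 of 30 (12 and 1, 1.97e-06), and these 6 lists held with an estimated correlation (adjusted p up to 0.0228). Luminal markers rose in 2 and fell in 0 of 22 (4 and 0 adjusted over the list alone, adjusted p = 0.028, adjusted p = 0.169 with an estimated correlation). In limma 711 genes passed, 259 higher and 452 lower, with median scaling 355 (148 higher), and with only the groups compared fitted 268 (85 higher).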

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

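Of the tests on the replication genes, those on the parental basal arrays and on a smaller response as a whole were chosen only after the result was seen. The results given here stood out because the lapatinib response differed between the parental and the resistant line by a test of the difference itself. At 1 µM 87 genes differed (limma, adjusted p under 0.05), and at 0.1 µM 1 gene did.

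The response at 1 µM was higher in resistant cells, on the log2 scale, for TARP (1.16), SSR3 (1.12), GINS4 (1.02), GSTA3 (0.97), CPS1 (0.97), ANKRD37 (0.93), PDIA3P1 (0.92), ACOX2 (0.89) and ALDOA (0.75). It was lower for PDK4 (-1.20), LRRC31 (-1.18), MAL (-1.05), BNIPL (-1.05), MIR503HG (-1.01), JPH2 (-1.01), ABCA1 (-0.92), SPRED1 (-0.88), FBXO32 (-0.83), CDC25B (-0.77), KIF20A (-0.70), ASNS (-0.70) and DDIT4 (-0.59). GSTA3 was not above background in parental cells, ACOX2 not in parental cells at 1 µM or in resistant cells, and ABCA1 not in untreated resistant cells, so these 3 are fitted values and not exact differences. The same holds for PDK4, above background on 1 of 3 untreated parental arrays. LRRC31 also passed at 0.1 µM (-1.02), but leaving out 1 array ended the call for 6 of the 12 arrays (adjusted p = 0.0527 to 0.148), as did a fit to only the groups compared (0.0613). The mean difference over a list at 1 µM was -0.24 for FOXO targets, -0.19 for mitosis, -0.18 for ATF4 and amino acid response, 0.11 for glycolysis and -0.15 for interferon response. At 0.1 µM it was -0.13 for FOXO targets, 0.29 for G1/S and DNA replication, 0.14 for mitosis, 0.15 for glycolysis, -0.13 for receptor tyrosine kinases and ERBB ligands, and -0.13 for interferon response. Of these 11 lists, only the replication list at 0.1 µM held with an estimated correlation (adjusted p = 0.0152).

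Replication genes fell less at 0.1 µM in resistant cells, with 33 of 34 members above 0 in the difference and a mean of 0.29 ± 0.05 (SE over arrays). The brighter parental basal arrays are not its whole source, since the gap between lines was larger at 0.1 µM than at 1 µM without any basal array (median 0.19, mean 0.24, SE 0.05, 29 of 34 members above 0). At the preset correlation the camera call held without any 1 of the 12 arrays (highest adjusted p = 8.8e-10). Arrays were not left out with an estimated correlation, so for that call reliance on 1 array is not excluded. The list means at 0.1 µM, minus the parental basal mean, were -0.60 to -0.48 on the parental and -0.28 to -0.15 on the resistant arrays. The resistant line kept 0.81 ± 0.04 (SE over genes) of the parental mitosis response and 0.43 ± 0.06 of the replication response, a difference of 0.38 ± 0.06. By these ratios a smaller response as a whole is not the whole source. It may be part, since 0.69 ± 0.10 was kept for FOXO targets, 0.69 ± 0.10 for nucleolar genes, 0.69 ± 0.18 for lysosomal genes and 0.89 ± 0.17 for luminal markers. The SEs of these ratios are over genes that share arrays and leave out the spread between arrays, so they overstate the precision. A difference between the lines themselves and an unrecorded difference in dose, time or growth between the cultures both stay open and were not tested.

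Other splits of the same arrays were counted for each comparison. With 10 splits of 3 against 3 a share under 0.05 cannot be reached, and in each of the 9 comparisons of that kind 1 split, the real one, gave as many genes. The real and highest other counts were 1415 and 0 (parental, 0.1 µM against basal), 3503 and 0 (1 µM against basal), 692 and 0 (1 µM against 0.1 µM), 916 and 21, 2892 and 0, and 711 and 1 (the same steps in the resistant line), and 1946 and 0, 2531 and 13, and 2663 and 0 (between lines at basal, 0.1 µM and 1 µM). Each other split mixed arrays of both groups, so any real change added to the spread within its sides. Low counts there were thus set in advance where the groups differ, and they say nothing on chance. For the difference in response at 1 µM, 7 of 100 splits gave 87 genes or more, up to 1798, and at 0.1 µM 14 of 100 gave 1 or more, up to 839, so chance is not excluded by these counts. The high counts point to a structure of the samples. At 1 µM the 6 other splits that gave 87 or more (759 to 1798) put unequal numbers of basal arrays, 2 apart, into the lines compared, so that the lapatinib response itself entered, while 42 splits with equal numbers gave 0 and 51 splits 1 apart gave at most 14. The splits therefore give no measure of chance for the difference, in either direction.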

How the results depend on the processing

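All 11 counts of changed genes stayed within 1.5 times under the authors' values, no background correction, offset 16 (chosen after seeing the data), both other filters, every kept probe (also chosen after) and the replicate block. All 366 results on named genes kept their side of the threshold with the authors' values and without background correction. Both settings are quantile normalizations of intensities that rank probes alike, so they are close to the same computation. The main fit was quantile-normalized too, so these settings test it little. The counts that moved further are given by setting, and except for the stricter threshold and for fewer arrays the cause was not tested. Median scaling aligns the arrays near background and leaves differences in brightness of the tested genes in. Median scaling gave 3642 (parental, 0.1 µM against basal), 379 (parental, 1 against 0.1 µM), 355 (resistant, 1 against 0.1 µM), 4167 (lines at basal) and 5 (difference at 0.1 µM). Of 366 named-gene results it ended 40 calls and turned 1, CCND1 between the untreated lines (-0.097, adjusted p = 0.546). The call of SRPK2 ended because another probe became the brightest, and it held with the first probe kept (1.72, chosen after seeing the data). Array weights gave 2266 (parental, 0.1 µM), 1486 (parental, 1 against 0.1 µM), 577 (resistant, 0.1 µM), 2 (difference at 0.1 µM) and 398 (difference at 1 µM), and put the lowest weight, 0.315, on resistant 0.1 µM replicate 3. An adjusted p under 0.01 gave 751, 232, 410, 1875 and 343 (parental 0.1 µM, parental step, resistant 0.1 µM, resistant 1 µM, resistant step), 1100, 1492 and 1644 (lines at basal, 0.1 and 1 µM), and 0 and 11 (differences). Fits to only the groups compared gave 1195 (parental step), 279 (resistant 0.1 µM), 268 (resistant step), 1479 (lines at 0.1 µM), 0 and 273 (differences). The mean of a gene's probes gave 2 (difference at 0.1 µM), and no intensity trend 51 (difference at 1 µM). The correlation of responses at 1 µM moved to 0.733 (offset 16), 0.726 (no filter) and 0.794 (stricter filter).

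Leaving out each array in turn gave 983 to 1105 (parental 0.1 µM), 2869 to 3089 (parental 1 µM), 311 to 451 (parental step), 598 to 1063 (resistant 0.1 µM), 2298 to 2485 (resistant 1 µM), 427 to 779 (resistant step), 1428 to 1569, 2015 to 2534 and 2055 to 2175 (lines at basal, 0.1 and 1 µM), and 0 to 3 and 32 to 67 (differences). Each of the 6 arrays moved the parental step by more than 1.5 times. Without resistant basal replicate 1, 2 or 3 the resistant 0.1 µM count was 599, 606 and 598, and without resistant 0.1 µM replicate 3, the array farthest from its group, 768. Without resistant 1 µM replicate 1, 2 or 3 the resistant step gave 462, 427 and 437. Every array but parental basal replicate 1 (62) and resistant basal replicate 1 (67) moved the difference at 1 µM that far. The correlations were 0.747 to 0.767 at 1 µM and 0.491 to 0.611 at 0.1 µM. At 1 µM only leaving out resistant basal replicate 1 (0.747) moved it by more than 0.0186. That limit is an SE of the correlation computed from these same leave-one-out values. For lists, an estimated correlation ended 30 of the calls, and fry ended 4 and added 65. The labels number replicates alike in each group, but no pairing of arrays by number was visible in the values. The deviations of 45 same-numbered pairs correlated at -0.203 to 0.166 (3 over 0.1), and 5 of 18 arrays correlated best with their own number. Whether same-numbered samples were handled together is not in the labels, and these correlations cannot show it. With the replicate number as a block no count moved over 1.5 times, 7 of 366 named-gene results lost the call and 1 list call was added. The chip block was not run, since chips are not named. Signal over background, 2.97 to 3.59 for the median gene, limits dim genes, and a gene near background can show only a lower bound.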

Other observations

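The tests on more genes peaking at 0.1 µM than independent lists allow and on KLF2 alone were chosen after the result was seen, the others before. DUSP1, EGR1, FOS and KLF2, named after their values were seen, rose at 0.1 µM and were lower again at 1 µM in both lines. DUSP1, a phosphatase that switches off MAPKs, rose by 1.32 (log2) at 0.1 µM and changed by -1.22 from 0.1 to 1 µM in parental cells, and by 1.32 and -1.27 in resistant cells. The transcription factor genes EGR1 (0.99 and -2.12 in parental, 0.69 and -2.23 in resistant cells), FOS (0.99 and -1.14, 1.02 and -1.56) and KLF2 (0.34 and -1.23, 0.48 and -0.77) did likewise. Other immediate early or feedback genes did not: no rise at 0.1 µM passed for JUN (adjusted p = 0.301 in parental and 0.919 in resistant cells), IER2 (0.428 and 0.67), ATF3 (0.29 and 0.501) or FOSB (0.268 and 0.704), DUSP4 fell in parental cells (adjusted p = 0.0381), and SPRY4, at its brightest probe, fell at both steps in both lines (parental group means 9.09, 8.23 and 6.92). The mean of SPRY4's probes ended its call from 0.1 to 1 µM in resistant cells (-0.29, limma adjusted p = 0.0712).

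These 4 genes were all that passed up and then down in both lines (4 in parental and 8 in resistant cells, of all genes tested), where independent lists would share 0.00254. Under median scaling, which lost KLF2, 3 were shared, where independent lists would share 0.000715. The coincidence of independent lists is thus excluded by a count of 4, or 3 without KLF2, but this says little. From basal to 0.1 µM the lines shared 302 rises where independent lists would share 29.7, so independence failed for rises in general. A shared cause other than the dose is not excluded by the count. Quantile normalization of the 0.1 µM arrays is not the source for EGR1, FOS and DUSP1, since all 3 kept both calls in both lines under median scaling, the only alternative without it. For KLF2 it may be, since its rise ended there (0.01, adjusted p = 0.954 in parental and 0.32, adjusted p = 0.109 in resistant cells). A response of the cells to the lower dose and a handling effect shared by the 0.1 µM samples both stay open for the other 3 genes, and neither was tested.

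Genes next to each other on a chromosome differed between the lines in the same direction. The Spearman correlation of the line difference between 12539 adjacent pairs was 0.165 ± 0.028 (SE), above the highest of 1000 shuffled orders (0.0292), and 0.0524 for the lapatinib response, a difference of 0.112 ± 0.030. It was 0.134, 0.134 and 0.127 with basal, 0.1 µM and 1 µM arrays alone. Signal shared between related neighbours is not the whole source, since without 733 pairs with like symbols the correlation was 0.156. Copy number or another regional difference between the lines, gained or selected on the way to resistance or by drift, may be the source, and these data hold no DNA measurement.

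In windows of 15 genes, 14 passed the highest of 50 shuffled orders (0.370), against 0 for the lapatinib response, and they formed 5 blocks. Lower in resistant cells were 21 genes from MTERF1 to SLC25A13 on chromosome 7 (median -0.32, 21 of one sign), 15 from TRMT13 to VAV3 on chromosome 1 (-0.39, 14), 16 from MAFA to EPPK1 on chromosome 8 (-0.31, 15) and 16 from SNORD14B to LDHC on chromosome 11 (-0.36, 13). Higher were 16 genes from CLIC3 to NELFB on chromosome 9 (0.34, 14). The block from TRMT13 to VAV3 also moved with lapatinib (median response 0.26, under the window threshold), while the other blocks lay between -0.07 and 0.10. On chromosome X, PAGE2B, PAGE2, VCF2 and PAGE5 lie side by side and VCF2 differed by 0.55 (mean over treatments), while the 6 measured genes on one side lay between -0.15 (APEX2) and 0.74 (TSR2) and the 6 on the other between -0.36 (KLF8) and 0.36 (MAGEH1).

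Of the 29 lists, 14 passed in no comparison. Their lowest adjusted p over the 11 comparisons was 0.0597 for cytosolic ribosomal proteins, 0.127 for fatty acid synthesis, 0.154 for apoptosis regulators, 0.161 for PI3K-AKT-mTOR components, 0.167 for drug efflux and drug metabolism, 0.198 for oestrogen receptor targets and 0.2 for basal and mesenchymal markers. It was 0.259 for 17q12 amplicon genes, 0.272 for HIF and hypoxia, 0.278 for the TCA cycle and oxidative phosphorylation and 0.624 for p53 targets. Markers of other cell types, 9 for leukocytes, 9 for fibroblasts and 8 for endothelium as measured, gave 0.256, 0.572 and 0.218. Among changed genes with several kept probes a called probe had the opposite sign in 13 of 1129 (parental, 1 µM), 7 of 891 (resistant, 1 µM), 4 of 636 (lines at basal) and 0 of 32 (difference at 1 µM). That count leaves out probes with no change, such as the other probes of SPRY4 and ERBB3, and the mean of a gene's probes ended 17 of 366 results on named genes. In a principal component analysis the first 3 components held 34.8%, 28.5% and 6.67% of the variance.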
